A study of Mus musculus with 9 samples.

How the data were processed

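Livers of 5-week-old mice were dissected and frozen, total RNA was depleted of ribosomal RNA, and strand-specific libraries were made, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, HTSeq 0.5.4p3 and DESeq2 1.0.19, and the mouse build mm10 (GRCm38), without saying which step each performed. The deposited values are a normalised signal per gene and library: read counts divided by 1 size factor per library, as their steps show. The annotation release, the filters and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Reads of near-identical genes (KRAB zinc finger genes and the Cyp2a, Cyp2b, Cyp2c, Gst, Mup, Saa and Slc22a families) may also be split between copies, and their levels are uncertain.

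In each library the values were whole multiples of the worth of 1 read, from which whole reads and size factors were recovered. With a tolerance of 0.1 read, 100% of values came out whole. Size factors ran from 0.545 to 1.25, and totals from 16266423 to 36161177 reads. The table held 22701 genes, of which 22257 (98.0%) had an identifier in GENCODE annotation of GRCm38, used for coordinates and gene types. A symbol shared by several genes affected 97 entries. A count of 0 allows up to 3 reads, and such limits cover counting error only. Reads from mitochondrial genes made up 3.83 to 5.51% of a library. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 52.9 to 136 between pairs), so no library was counted as a copy of another.

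Groups were taken from the genotype labels. The test of each comparison was limma 3.58.1 in R 4.3.3 with a mean trend, on log2(deposited value + 1), for the 13845 genes with a mean of at least 10 over the 9 libraries. All 4 groups entered 1 fit (5 residual and 3.13 prior degrees of freedom), so the lone HP1ab_KO library was assumed to vary like the other groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Differences are on the log2(value + 1) scale, which understates those of genes with low values. Gene lists fixed beforehand (29) were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists, and camera with an estimated correlation and fry were run beside it. The tests, lists, naming rule and most alternatives were set before the data were examined.

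The genes named were the targeted genes and, for each comparison with WT, up to 10 per direction with the widest log2 difference among called genes whose libraries all lay on one side of the reference libraries. A mean of at least 50 in the higher group was required, and unnamed gene models and the listed genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were left out, other genes on the sex chromosomes not. Up to 5 per direction were taken for the other comparisons, and at most 2 members per list, by smallest p, against WT. A gene that met this rule for HP1ag_KO against WT is not reported here. Because limma called 0 genes in each comparison (324 to 2240 at an unadjusted p under 0.05), as did edgeR, the rule was applied to the calls of DESeq2, a choice made after the results were seen. Wald tests of DESeq2 1.42.0 and quasi-likelihood tests of edgeR 4.0.16 were run on the recovered reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

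The tests were tried on simulated counts with known changes, over 13751 genes. For HP1ag_KO against WT, limma recovered 51.0% of 2-fold and 91.8% of 4-fold changes with 7 false calls, edgeR 53.1% and 93.8% with 9, and DESeq2 69.4% and 96.9% with 36. For HP1a_KO against WT, limma recovered 34.7% and 82.5% with 6 false calls, and DESeq2 62.2% and 91.8% with 32. For HP1ab_KO against WT, limma recovered 11.2% and 76.3% with 6 false calls, and DESeq2 32.7% and 83.5% with 49. A simulated list of 100 genes raised 1.3-fold had a camera p of 1.3e-21, and 2 of 200 unchanged lists had a p under 0.05. The simulated genes were drawn independently of each other and the unchanged lists at random. This run therefore cannot tell how often camera calls real lists, whose members vary together. Alternatives covered the pseudocount (0.5 and 5), the filter (none and a mean of 50), scaling by TMM or to equal totals, limma without the trend, with robust shrinkage or with array weights, the Xist level as a covariate, fits of only the groups compared, the count tests, and leaving out each replicate. An intended term for the sequencing project was not run, because no column ties a library to a project.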

Results

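RNA was sequenced from the livers of 9 mice aged 5 weeks, on a background that the labels give as C57BL/6 and 129svPas. The groups were WT (3 livers), mice without HP1α (HP1a_KO, 2 livers), mice without HP1α whose HP1β gene was deleted in the liver (HP1ab_KO, 1 liver) and mice without HP1α whose HP1γ gene was deleted in the liver (HP1ag_KO, 3 livers). HP1α, HP1β and HP1γ are chromatin proteins that bind methylated histone tails in heterochromatin and are encoded by Cbx5, Cbx1 and Cbx3. The series title concerns a tumour-suppressing role of these proteins in mouse liver, and the comparisons ask how liver transcripts differ when 1 or 2 of them are missing. Libraries held 26375545 to 36161177 reads in genes, except HP1a_KO replicate 1 with 16266423. Values are normalised read counts, given as mean ± SD with n = 3 for WT and HP1ag_KO and n = 2 for HP1a_KO. HP1ab_KO has a single library, so its values carry no SD and its differences have no replicate check. The labels name each library by an animal number and say no more about litters or sex. The p-values of single genes measure the spread between these samples. Those of gene lists at the preset correlation of 0.01 also take the members as nearly independent. Estimated correlations were, for example, 0.031 for KRAB zinc finger genes, 0.546 for interferon-stimulated genes and 0.611 for male-biased genes. With estimated correlations 0 lists passed in any comparison.

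Hepatocyte transcripts led every library. Alb, which encodes albumin, took 8.03% of reads on average (5.89 to 9.34%), Apob 1.92%, mt-Co1 1.91% and Serpina3k 1.41%. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in each library, with Ddx3y between 3036 and 4549, Eif2s3y between 1215 and 1834, Kdm5d between 462 and 821, and Uty between 826 and 1385. Xist, the RNA of the inactive X chromosome, lay between 0.889 and 14.6. These are few reads, as 0.889 is the worth of 1 read in WT replicate 1. Its mean was 4.36 ± 5.96 in WT and 10.5 ± 4.62 in HP1ag_KO. As a covariate, here and below, the Xist level thus carries counting error and partly follows the groups. Changes under it cannot show a dependence on sex. The first principal component (24.98% of the variance) ran from -41.2 in HP1a_KO replicate 1 to 44.7 in HP1ag_KO replicate 2. The second (22.8%) ran from -44.8 in HP1ag_KO replicate 1 to 50.3 in WT replicate 1, and these 2 libraries lay far from the others of their groups.

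Transcripts of each deleted gene were lower but still present in the livers labelled as lacking it. Cbx5 (ENSMUSG00000009575, chromosome 15, 103191544 to 103239816, build GRCm38) had 1235 ± 279 reads in WT, 538 ± 53.3 in HP1a_KO, 663 in HP1ab_KO and 743 ± 75.8 in HP1ag_KO. On the log2 scale these groups lay at 44.2%, 54.6% and 61.0% of WT. Cbx1 (ENSMUSG00000018666, chromosome 11, 96789127 to 96808640) had 917 ± 146 reads in WT and 217 in HP1ab_KO, which is 24.0% of WT, against 614 ± 222 in HP1a_KO and 753 ± 89.7 in HP1ag_KO. Cbx3 (ENSMUSG00000029836, chromosome 6, 51470360 to 51483704) had 605 ± 59.7 reads in WT and 349.7 ± 27.5 in HP1ag_KO, which is 57.9% of WT, against 591 ± 25.9 in HP1a_KO and 542 in HP1ab_KO. DESeq2 gave adjusted p = 0.00012 for Cbx5 in HP1a_KO, 0.026 for Cbx5 in HP1ag_KO, 0.327 for Cbx5 in HP1ab_KO, 6.89e-07 for Cbx1 in HP1ab_KO and 4.19e-05 for Cbx3 in HP1ag_KO. The limma adjusted p of the same 5 differences lay between 0.198 and 0.999, and reads from parts of a gene outside its deletion, or from cells that keep it, count toward these values.

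**Figure D1:**
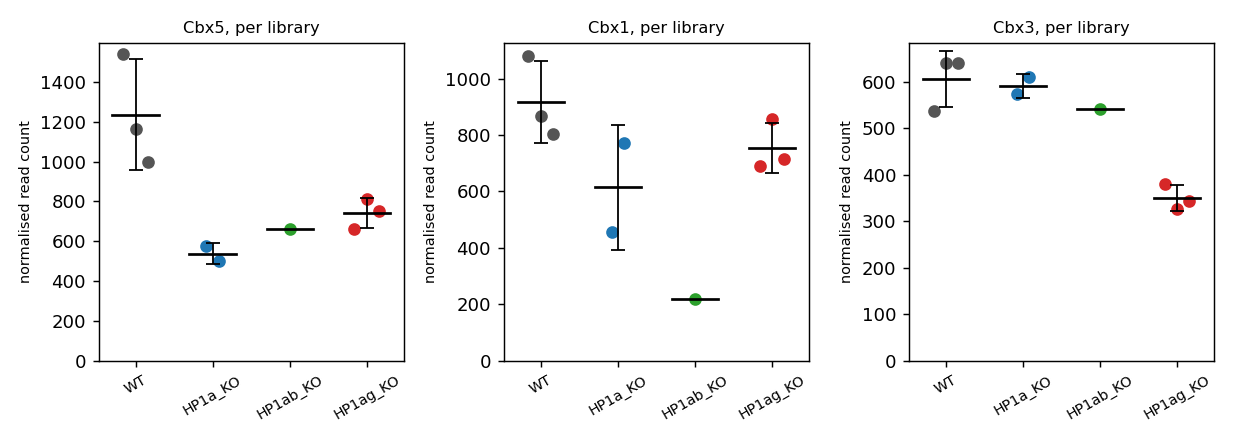
Normalised read counts (linear axis from 0) of Cbx5, Cbx1 and Cbx3 in each library, grouped by genotype. Points are libraries, long bars are group means and error bars are SD where a group has more than 1 library. The 3 HP1ag_KO libraries sit between 326 and 380 for Cbx3, below the lowest WT library at 536.

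The comparison of HP1ag_KO with WT asks what loss of HP1α with liver HP1γ does. Lists are tested as sets here and below: the counts of members give the sign of each difference, passed or not, the median covers all members, and limma called 0 members over all genes. KRAB zinc finger genes, which encode DNA-binding repressors, were higher as a set in HP1ag_KO, with 108 of 141 members higher and a median log2 difference of 0.21 (limma camera, adjusted p = 9.39e-09, and adjusted p = 0.135 with an estimated correlation). Zfp433 had 296 ± 23.6 reads against 165 ± 13.7 in WT, and Zfp84 441 ± 36.7 against 285 ± 35.5. Interferon-stimulated genes, the antiviral program, were higher in 43 of 45 members by a median of 0.35 (adjusted p = 4.9e-12, and adjusted p = 0.647 with an estimated correlation). The libraries of the 2 groups overlapped even so. Mean log2 values of these genes, centred per gene, were 0.22, -0.43 and -0.14 in WT replicates 1 to 3 and 0.06, 0.24 and 0.44 in HP1ag_KO. Mx2 stood at 372 ± 35.2 against 193 ± 44.3 and Gbp3 at 671 ± 142 against 396 ± 47.3. Genes of the NRF2 antioxidant response were lower in 21 of 28 members, with a median of -0.28 (adjusted p = 1.06e-06, and adjusted p = 0.135 with an estimated correlation). Among them the glutathione synthesis gene Gclm stood at 4755 ± 309 against 6385 ± 557 and Ugdh at 2118 ± 585 against 3842 ± 288.

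Sex-biased liver genes moved apart. Genes normally higher in female liver were higher in 29 of 35 members by a median of 0.73 (adjusted p = 9.39e-09, and adjusted p = 0.647 with an estimated correlation). The magnesium transporter Nipal1 stood at 611 ± 217 against 133 ± 27.2 and Cyp2a4 at 3348 ± 2884 against 242 ± 301. Genes normally higher in male liver were lower in 33 of 35 members, with a median of -0.87 (adjusted p = 1.58e-07, and adjusted p = 0.647 with an estimated correlation). Susd4, a complement regulator, had 32.3 ± 19.7 against 335 ± 209, whereas Mup21, a major urinary protein, was higher at 15512 ± 11909 against 1526 ± 1005. Without HP1ag_KO replicate 1 the male-biased median was -0.28, and without WT replicate 2 the interferon median was 0.16. Markers of Kupffer cells, the liver's macrophages, were also higher, in 13 of 16 members by a median of 0.20 (adjusted p = 0.00801, and adjusted p = 0.677 with an estimated correlation). Il18bp stood at 489 ± 77.9 against 328 ± 16.5 and Cd68 at 195 ± 46.0 against 146 ± 14.7. Stellate cell and fibrosis markers were higher in 17 of 25 by 0.21 (adjusted p = 0.0266, and adjusted p = 0.677 with an estimated correlation). Colec11 stood at 1083 ± 37.1 against 831 ± 103. Fatty acid and triglyceride synthesis genes were higher in 19 of 27 by 0.07 (adjusted p = 0.0266, and adjusted p = 0.647 with an estimated correlation). The lipase Pnpla3 stood at 92.8 ± 35.2 against 27.9 ± 11.4. These last 3 calls each ended without at least 1 library. The Kupffer median was 0.03 without HP1ag_KO replicate 1 (adjusted p = 0.526) and 0.33 without HP1ag_KO replicate 2. The stellate median was 0.02 without WT replicate 1 (0.638), 0.12 without HP1ag_KO replicate 1 (0.0544) and 0.15 without HP1ag_KO replicate 3 (0.0976). The fatty acid median was 0.10 without WT replicate 1 (0.132), 0.13 without WT replicate 3 (0.0614), 0.08 without HP1ag_KO replicate 2 (0.191) and 0.09 without HP1ag_KO replicate 3 (0.233), and was 0.17 without WT replicate 2 and 0.16 without HP1ag_KO replicate 1. With the Xist level as a covariate the stellate (0.22, 0.0734) and fatty acid (0.08, 0.275) calls ended and the NRF2 median was -0.42. That covariate rests on few reads, so these changes cannot be read as an effect of sex. No other list passed in this comparison (smallest adjusted p = 0.0512, for fetal liver and hepatocellular carcinoma markers). Terms for runs of neighbouring animal numbers changed these calls. The stellate (0.02, camera adjusted p = 0.313) and fatty acid (0.12, 0.0533) calls ended. Cell cycle genes (-0.17, 0.0477), erythroid markers (-0.69, 0.0056) and acute phase proteins (0.26, 0.0477) passed, all at the preset correlation.

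Single genes that DESeq2 called in HP1ag_KO, with every library on one side of every WT library, included Dpy19l3 (ENSMUSG00000043671, chromosome 7, 35685165 to 35754454), which encodes a tryptophan mannosyltransferase. It had 1009 ± 296 reads against 236 ± 55.1 (log2 difference 2.08 ± 0.23 SE, DESeq2 adjusted p = 9.21e-13, limma adjusted p = 0.146). The unprocessed pseudogene RP24-194K24.6 (ENSMUSG00000098330, chromosome 7, 14724656 to 14724904) had 97.1 ± 23.1 against 20.4 ± 3.85. Also higher were the ribonuclease P subunit Rpp40 (695 ± 271 against 175 ± 38.9), the imprinted noncoding RNA Meg3 (94.5 ± 56.1 against 19.08 ± 2.25) and the acyltransferase Acnat2 (1044 ± 78.9 against 327 ± 200.4). The cytochrome P450 Cyp2b9 and the organic anion transporters Slc22a26, Slc22a27 and Slc22a29 were higher in each HP1ag_KO library, but 1 library dominated. Cyp2b9 had 6684, 339.8 and 808 reads in HP1ag_KO replicates 1, 2 and 3 against 82.0 ± 64.0 in WT, and Slc22a27 had 1009.8, 74.0 and 159 against 20.9 ± 14.4. Slc22a26 stood at 999 ± 1489.7 against 37.9 ± 26.0, with a log2 difference of 3.43 ± 1.14 SE that was 1.97 without HP1ag_KO replicate 1, and Slc22a29 at 57.1 ± 47.0 against 6.92 ± 5.77. Reads may be shared within the Cyp2b, Cyp2a, Slc22a and Mup families, so their levels are uncertain.

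Lower genes in HP1ag_KO included Nox4 (ENSMUSG00000030562, chromosome 7, 87246096 to 87398710), an NADPH oxidase that makes hydrogen peroxide. It had 186 ± 70.0 reads against 774 ± 116 (log2 difference -2.10 ± 0.25 SE, DESeq2 adjusted p = 9.04e-11, limma adjusted p = 0.146), and limma called it without HP1ag_KO replicate 1 (-2.38). The carboxylesterase Ces4a had 65.1 ± 31.2 against 317 ± 56.3 and Olfm3 24.2 ± 4.37 against 126 ± 61.0. The proteoglycan genes Cspg5 and Gpc1 and the collagen gene Col12a1 were lower too, Cspg5 at 28.1 ± 20.7 against 91.5 ± 16.5, Gpc1 at 96.9 ± 3.37 against 208 ± 75.7 and Col12a1 at 62.8 ± 5.59 against 156 ± 52.0. Dact1 stood at 65.5 ± 18.9 against 205 ± 108 and the ubiquitin ligase Rnf152 at 428 ± 121 against 848 ± 239, with a log2 difference of -0.99 ± 0.26 SE that was -0.57 with the Xist level as a covariate. Across 13845 genes limma called 0 (smallest adjusted p = 0.146), with 1050 at an unadjusted p under 0.05. Unchanged genes would give 692 on average, here and below, but that average says nothing of its spread when genes vary together. Other splits of the WT and HP1ag_KO libraries gave 213 to 1363 such genes. The quasi-likelihood test of edgeR called 0 and DESeq2 99 (51 higher and 48 lower), and 40 without WT replicate 1. Adjusted over the list alone, limma called 1 KRAB gene (Zfp433), 2 interferon-stimulated genes (Mx2 and Gbp3), 6 NRF2 genes, 8 female-biased genes, 1 male-biased gene (Susd4) and 1 gene of fatty acid synthesis (Pnpla3). In lists that did not pass it called Cbx3, Cbx5 and Glul lower and Gpc3 higher, the last 2 chosen after their values were seen.

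**Figure D2:**
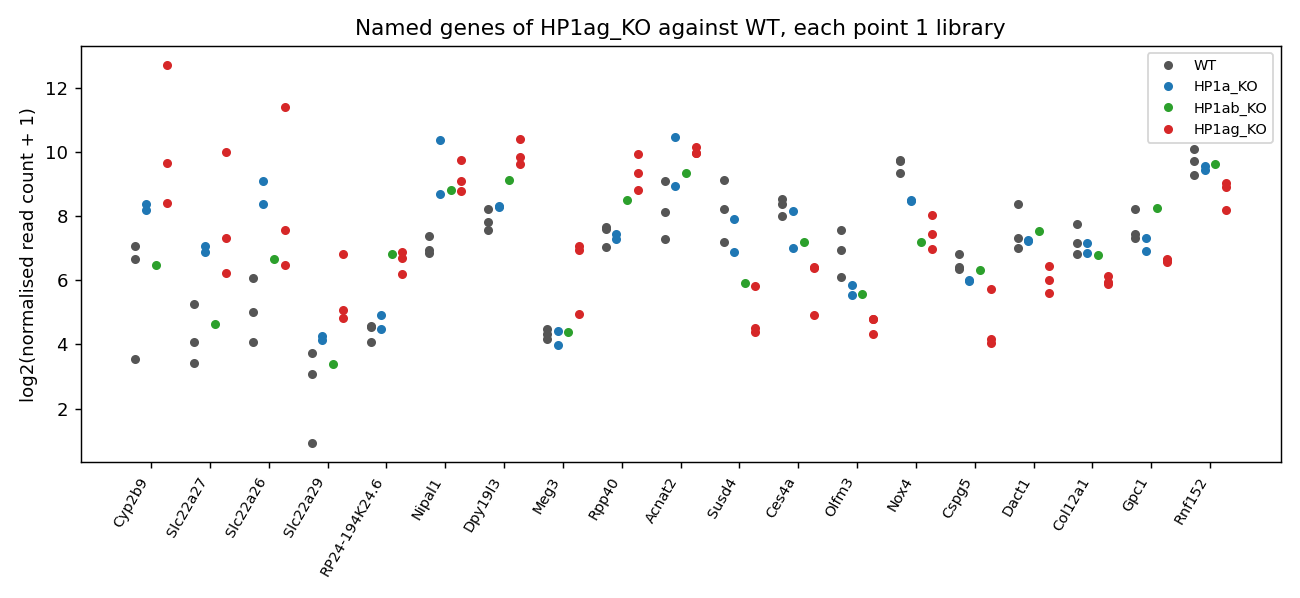
Log2(normalised read count + 1) of the genes named for HP1ag_KO against WT, with 1 point per library and 1 colour per genotype. From Cyp2b9 to Acnat2 all HP1ag_KO libraries lay above all WT libraries, and from Susd4 to Rnf152 below; for Nox4 the HP1ag_KO libraries lay between 125 and 262 reads and the WT libraries between 640.0 and 848.

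**Figure D3:**
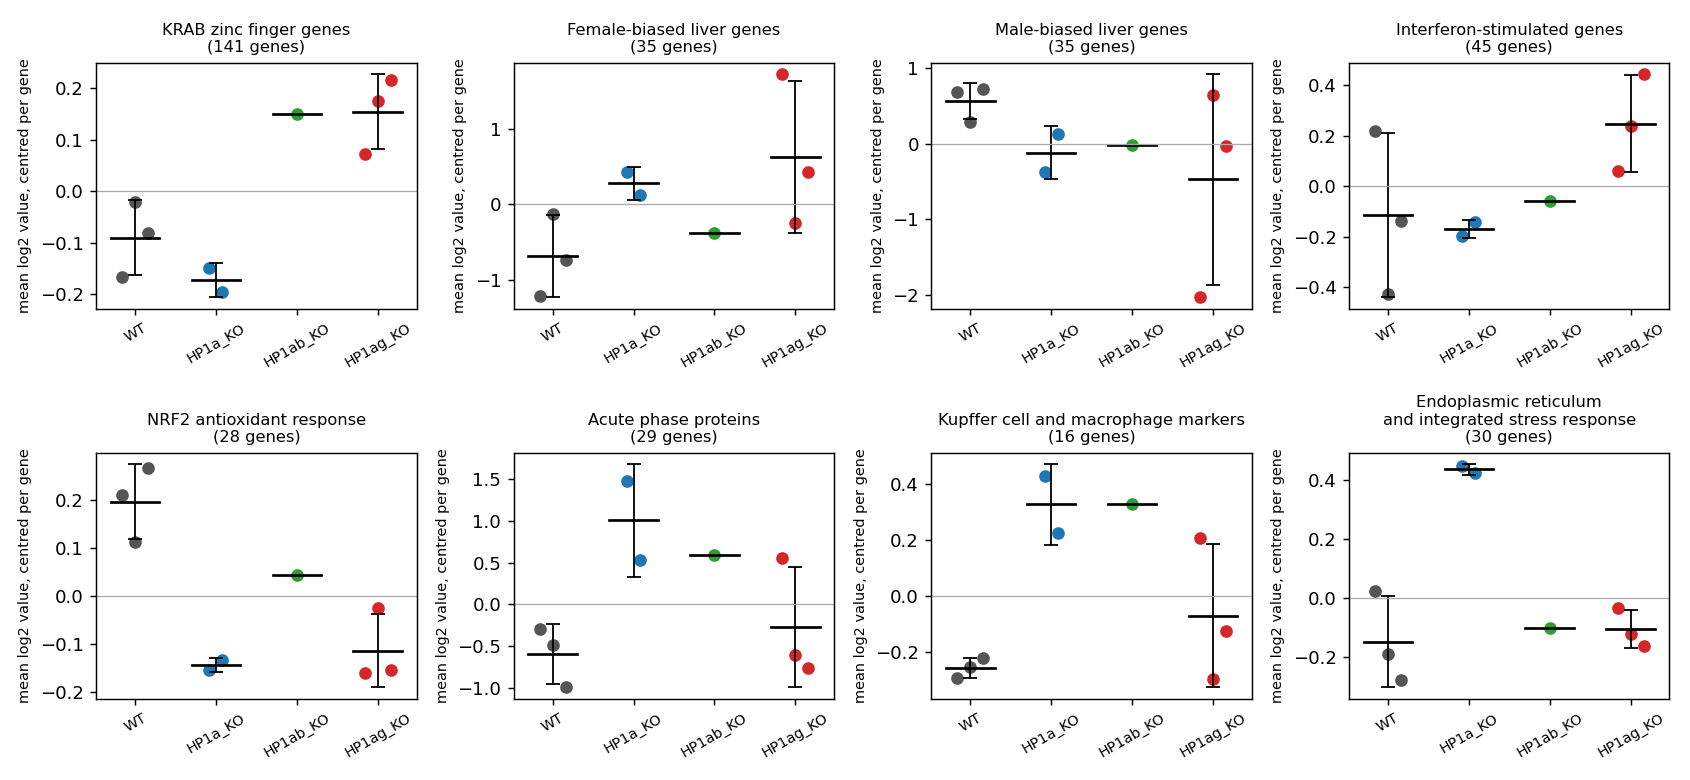
Mean log2 value of the members of 8 gene lists, centred per gene on its mean over the 9 libraries, for each library (points), with group means (long bars) and SD (error bars, groups of more than 1). The single HP1ab_KO library and the 3 HP1ag_KO libraries lie above all WT and HP1a_KO libraries for KRAB zinc finger genes, and HP1ag_KO replicate 1 lies far below the rest for male-biased genes.

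The comparison of HP1a_KO with WT asks what loss of HP1α alone does. Acute phase proteins, which the liver secretes in inflammation, were higher in 27 of 29 members by a median log2 difference of 1.18 (camera, adjusted p = 8.62e-12, and adjusted p = 0.373 with an estimated correlation). Orosomucoid Orm1 had 28941 ± 14175 reads against 11982 ± 858 in WT, and serum amyloid Saa2 72373 ± 66403 against 423 ± 172. The acute phase median was 0.65 without HP1a_KO replicate 1. Kupffer cell markers were higher in all 16 members by 0.56 (adjusted p = 2.99e-11, and adjusted p = 0.373 with an estimated correlation). The iron exporter Slc40a1 stood at 8055 ± 291 against 5803 ± 299.9 and Il18bp at 613 ± 194 against 328 ± 16.5. Stellate cell and fibrosis markers were higher in 24 of 25 by 0.31 (adjusted p = 1.41e-07, and adjusted p = 0.373 with an estimated correlation). The collagen gene Col1a1 stood at 1218 ± 244 against 438 ± 137 and Col1a2 at 1810.2 ± 203 against 980.1 ± 183. The stellate median was 0.14 without WT replicate 1 and 0.54 without WT replicate 2.

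Stress and sterol genes were also higher in HP1a_KO. Endoplasmic reticulum and integrated stress response genes were higher in 20 of 30 by 0.16 (adjusted p = 0.000448, and adjusted p = 0.373 with an estimated correlation). Sesn2 stood at 499 ± 78.5 against 207 ± 25.5 and Aldh1l2 at 23.3 ± 8.59 against 4.65 ± 1.08, and the list median was 0.25 without WT replicate 3. Cholesterol biosynthesis genes were higher in 20 of 24 by 0.45 (adjusted p = 5.97e-05, and adjusted p = 0.519 with an estimated correlation). Hmgcs1 stood at 14960.2 ± 8718 against 5486 ± 1732 and Dhcr7 at 1647 ± 299 against 895 ± 127. Without HP1a_KO replicate 1 the cholesterol median was 0.09 (adjusted p = 0.370), and without HP1a_KO replicate 2 it was 0.86. Immediate early genes were higher in 15 of 19 by 0.35 (adjusted p = 0.0115, and adjusted p = 0.519 with an estimated correlation). The call ended without WT replicate 1 (0.32, adjusted p = 0.106) and without WT replicate 2 (0.33, adjusted p = 0.154), with a median of 0.54 without WT replicate 3. Fetal liver and hepatocellular carcinoma markers were higher in 21 of 28 by 0.33 (adjusted p = 0.00585, and adjusted p = 0.443 with an estimated correlation), although glutamine synthetase Glul was lower, at 16548 ± 455 against 25610.3 ± 305, and the call ended without WT replicate 1 (0.31, adjusted p = 0.179). S100a11 in the same list stood at 38.4 ± 8.02 against 12.0 ± 1.56.

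Female-biased genes were higher in HP1a_KO in 29 of 35 members by 0.68 (adjusted p = 0.00018, and adjusted p = 0.519 with an estimated correlation). The prolactin receptor Prlr stood at 5115 ± 291 against 2672 ± 532. Male-biased genes were lower in 30 of 35, with a median of -0.54 (adjusted p = 0.00696, and adjusted p = 0.829 with an estimated correlation), and Selenbp2 stood at 2913 ± 3197 against 31795 ± 5966. The call ended without WT replicate 1 (-0.42, adjusted p = 0.0630) and without HP1a_KO replicate 1 (-0.34, adjusted p = 0.0999). NRF2 genes were lower in 21 of 28, with a median of -0.26 (adjusted p = 0.00356, and adjusted p = 0.373 with an estimated correlation) and the glutathione transferases Gstm3 at 572 ± 209 against 1044 ± 65.0 and Gsta1 at 13.5 ± 9.40 against 54.9 ± 21.7. KRAB zinc finger genes were lower in 93 of 141, with a median of -0.12 (adjusted p = 0.0236, and adjusted p = 0.508 with an estimated correlation). That call ended without WT replicate 2 (-0.09, adjusted p = 0.0917) and without HP1a_KO replicate 2 (-0.11, adjusted p = 0.120). No other list passed (smallest adjusted p = 0.168, for bile acid synthesis and transport).

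The cytochrome P450 Cyp2c39 (ENSMUSG00000025003, chromosome 19, 39510862 to 39568529) showed the widest log2 difference among the genes named for this comparison, with 2511 ± 1057 reads in HP1a_KO against 54.8 ± 25.9 in WT (log2 difference 5.53 ± 0.51 SE, DESeq2 adjusted p = 7.92e-28, limma adjusted p = 0.0585). It was also high in HP1ab_KO (1690.0) but not in HP1ag_KO (108 ± 59.9), and limma called it as its only gene with a pseudocount of 5 or with array weights. Proteinase 3 Prtn3 was higher, at 205 ± 104 against 19.6 ± 10.0, S100a8 at 77.3 ± 20.5 against 15.1 ± 2.61 and Saa3 at 1789 ± 1907 against 139.9 ± 52.9. The 2 HP1a_KO libraries had 3137 and 440.5 reads of Saa3, and its log2 difference of 3.13 ± 0.71 SE was 1.72 without replicate 1 and 4.55, a limma call, without replicate 2. The serine synthesis gene Phgdh had 64.7 ± 14.9 against 8.40 ± 5.16, the citrate transporter Slc13a5 114 ± 69.8 against 16.7 ± 12.8, the crystallin Crybb3 162 ± 77.7 against 28.6 ± 16.1, lubricin Prg4 1163 ± 469.7 against 317 ± 220.2 and the stress cytokine Gdf15 173 ± 34.2 against 54.5 ± 30.8. Nipal1 had 1330.2 and 409 reads in the 2 HP1a_KO libraries, and its log2 difference of 2.48 ± 0.47 SE was 1.63 without replicate 1.

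Lower in HP1a_KO were the glutathione transferase Gsta2 (31.7 ± 7.09 against 166 ± 80.5), the cytochrome P450 Cyp2a5 (3256 ± 934 against 12385 ± 8305), hemojuvelin Hfe2 (779 ± 165 against 1311 ± 59.9), the junction protein gene Cgn (437 ± 5.39 against 750.4 ± 78.5) and Nox4 (357 ± 9.29 against 774 ± 116). Ly6a had 138 ± 24.5 against 285 ± 33.8, Cpsf4l 36.2 ± 11.1 against 93.4 ± 16.2, the dynein heavy chain Dync2h1 220.0 ± 10.1 against 364 ± 41.3, and Emc9 216 ± 61.1 against 385 ± 34.5, with a log2 difference of -0.86 ± 0.19 SE that was -0.57 without HP1a_KO replicate 1. Over all genes limma called 0 (smallest adjusted p = 0.0585), with 1404 at an unadjusted p under 0.05 (692 by chance), edgeR called 0 and DESeq2 89 (64 higher and 25 lower). The DESeq2 count was 4 without HP1a_KO replicate 1, the library with the fewest reads, 255 without WT replicate 1, 59 without WT replicate 2 and 35 without WT replicate 3. Adjusted over the list alone, limma called 13 acute phase genes, 9 Kupffer cell markers, 8 stellate cell markers, 4 NRF2 genes (Gstm3, Gsta1, Gstm1 and Gsta2, all lower), 4 stress response genes (Sesn2, Aldh1l2, Phgdh and Mthfd2, all higher), 5 fetal liver markers (S100a11, Cd44, Lcn2 and Gpc3 higher and Glul lower) and 2 female-biased genes (Nipal1 and Prlr). In lists that did not pass it called Cbx5 lower and Cyp2c39, S100a8, Cdh5, Maf and Bicc1 higher. Those outside the naming rule were chosen after their values were seen.

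The comparison of HP1ab_KO with WT sets 1 liver against 3 and asks what loss of HP1α with liver HP1β does. Clec2h (ENSMUSG00000030364, chromosome 6, 128662385 to 128677374), a C-type lectin gene, had 4.79 reads in HP1ab_KO against 396 ± 217 in WT (log2 difference -5.96 ± 0.69 SE, DESeq2 adjusted p = 2.21e-09, limma adjusted p = 0.326). Nox4 was lower at 146, the lipid droplet gene Fitm1 at 24.8 against 129 ± 23.5, the receptor Ror1 at 48.7 against 156 ± 41.2 and Ugt3a2 at 7478 against 12428 ± 358. Higher were Cyp2c39, the pseudogene RP24-194K24.6 (111 against 20.4 ± 3.85), the trefoil factor Tff3 (717 against 184 ± 70.0), Wdfy1 (703 against 283 ± 42.4) and Tmem176a (4325 against 2284 ± 380.2). Limma called 0 genes here (512 at an unadjusted p under 0.05, below the 692 that come by chance), edgeR 0 and DESeq2 11 (5 higher and 6 lower, Cbx1 among the lower), and 19 without WT replicate 1 or 18 without WT replicate 3.

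In HP1ab_KO, KRAB zinc finger genes were higher in 106 of 141 members by a median of 0.22 (camera, adjusted p = 8.39e-06, and adjusted p = 0.462 with an estimated correlation). Rsl1 stood at 87.1 against 42.5 ± 3.66 while Zfp473 was lower at 1.60 against 9.90 ± 2.80. Kupffer cell markers were higher in 15 of 16 by 0.53 (adjusted p = 3.75e-12, and adjusted p = 0.462 with an estimated correlation). Cd68 stood at 280.5 against 146 ± 14.7 and the complement gene C1qa at 1948 against 1212 ± 107. Acute phase proteins were higher in 28 of 29 by 0.65 (adjusted p = 2.17e-08, and adjusted p = 0.462 with an estimated correlation). The lipopolysaccharide-binding protein gene Lbp stood at 5510.4 against 2477 ± 393. Stellate cell markers were higher in 21 of 25 by 0.34 (adjusted p = 2.05e-06, and adjusted p = 0.462 with an estimated correlation). Vimentin Vim stood at 883 against 481 ± 37.0. Sinusoidal endothelial markers were higher in 14 of 16 by 0.19 (adjusted p = 0.00283, and adjusted p = 0.643 with an estimated correlation), or 0.12 without WT replicate 2. Male-biased genes were lower in 30 of 35, with a median of -0.48 (adjusted p = 0.00423, and adjusted p = 0.857 with an estimated correlation). Calls for NRF2 genes (-0.20, adjusted p = 0.0187, and adjusted p = 0.462 with an estimated correlation), erythroid markers (1.33, adjusted p = 0.0235, and adjusted p = 0.682 with an estimated correlation) and fetal liver markers (0.18, adjusted p = 0.0494, and adjusted p = 0.643 with an estimated correlation) each ended without 1 WT library. Without WT replicate 3 the NRF2 median was -0.13 (adjusted p = 0.0766), and without WT replicate 1 the erythroid median was 0.84 (0.243) and the fetal median 0.15 (0.340). The erythroid call also ended with the Xist level as a covariate (0.0947), as did the fetal call (0.0777), which TMM scaling ended too (0.0621). Adjusted over the list alone, limma called 5 Kupffer cell markers (Cd68, C1qa, C1qb, C1qc and Cd5l, the last 3 chosen after their values were seen) and 1 stellate cell marker (Vim), all higher. In lists that did not pass it called Cbx1, Fitm1 and Gna14 lower and Cyp2c39 higher, Gna14 chosen after its values were seen.

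The comparison of HP1ag_KO with HP1a_KO asks what deleting HP1γ in the liver adds to the loss of HP1α. KRAB zinc finger genes were higher in 115 of 141 members by a median of 0.31 (adjusted p = 2.2e-09, and adjusted p = 0.21 with an estimated correlation; fry adjusted p = 0.0436). Interferon-stimulated genes were higher in 41 of 45 by 0.40 (adjusted p = 6.03e-08, and adjusted p = 0.897 with an estimated correlation). Acute phase proteins were lower in 26 of 29, with a median of -0.95 (adjusted p = 1.75e-06, and adjusted p = 0.897 with an estimated correlation), or -0.44 without HP1a_KO replicate 1. Kupffer cell markers were lower in 15 of 16, with a median of -0.37 (adjusted p = 0.000112, and adjusted p = 0.897 with an estimated correlation), or -0.23 without HP1a_KO replicate 1. Stress response genes (24 of 30 lower, -0.18, adjusted p = 0.00976), stellate cell markers (18 of 25 lower, -0.25, adjusted p = 0.0112) and cholesterol biosynthesis genes (18 of 24 lower, -0.37, adjusted p = 0.0205) were lower as well, each with adjusted p = 0.897 with an estimated correlation. Without HP1a_KO replicate 1 these 3 calls ended, at -0.16 (adjusted p = 0.0698), -0.15 (0.103) and, with the sign turned, 0.10 (0.863). The stress response call also ended without HP1ag_KO replicate 3 (-0.09, 0.0548) and the cholesterol call without HP1ag_KO replicate 1 (-0.17, 0.299). The cholesterol median was -0.78 without HP1a_KO replicate 2, the stellate median -0.14 without HP1ag_KO replicate 2, and the stress response median -0.32 and -0.30 without HP1ag_KO replicates 1 and 2. With the Xist level as a covariate the acute phase median was -0.52.

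Genes higher in HP1ag_KO than in HP1a_KO included Mup21 (15512 ± 11909 against 1040.1 ± 506), the hepcidin gene Hamp2 (1609.9 ± 1183 against 223 ± 99.8), the kinase Ptk6 (74.8 ± 51.9 against 12.3 ± 6.98), Meg3 (94.5 ± 56.1 against 17.4 ± 3.93) and Wdr72, with 2.73, 63.9 and 241 reads in the 3 HP1ag_KO libraries against 1.35 ± 0.689. Lower genes included Cyp2c39, Saa3 (83.0 ± 15.5 against 1789 ± 1907), the protease inhibitor A2m (7.08 ± 5.47 against 411 ± 410.4), Susd4 (32.3 ± 19.7 against 177 ± 86.8) and the serine synthesis gene Psat1 (51.7 ± 28.5 against 254 ± 58.8). The log2 difference of Saa3 was -3.83 ± 0.71 SE, or -2.41 and -5.24 without HP1a_KO replicates 1 and 2, and limma called it without HP1a_KO replicate 2 and Cyp2c39 without HP1ag_KO replicate 1. Limma called 0 genes (smallest adjusted p = 0.127), with 2240 at an unadjusted p under 0.05 (692 by chance), edgeR called 0 and DESeq2 465 (226 higher and 239 lower). The DESeq2 count was 26 without HP1a_KO replicate 1, 77 without HP1a_KO replicate 2, 148 without HP1ag_KO replicate 2 and 200 without HP1ag_KO replicate 3. Adjusted over the list alone, limma called 11 acute phase genes (all lower), 4 KRAB genes (Zfp433, Zkscan3, Zfp329 and Zfp866, all higher), 2 interferon-stimulated genes (Mx2 and Stat2, higher), 3 stellate cell markers (Tgfb1, Bgn and Col1a1, lower), 2 Kupffer cell markers (Slc40a1 and Cd163, lower) and 2 stress response genes (Mthfd2 and Sesn2, lower), whose names were chosen after their values were seen. Lists that did not pass held 2 more such calls higher and 10 lower.

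HP1ab_KO against HP1a_KO asks what deleting HP1β in the liver adds, with 1 liver against 2. KRAB zinc finger genes were higher in 118 of 141 members by a median of 0.32 (adjusted p = 1.98e-13, and adjusted p = 0.0983 with an estimated correlation). Stress response genes were lower in 28 of 30, with a median of -0.40 (adjusted p = 4.31e-07, and adjusted p = 0.128 with an estimated correlation), and immediate early genes in 17 of 19, with a median of -0.46 (adjusted p = 0.000134, and adjusted p = 0.855 with an estimated correlation). Cholesterol biosynthesis genes (23 of 24 lower, -0.36, adjusted p = 6.06e-06), female-biased genes (28 of 35 lower, -0.49, adjusted p = 0.00165) and acute phase proteins (21 of 29 lower, -0.36, adjusted p = 0.04) were lower too, each with adjusted p = 0.99 with an estimated correlation. These 3 calls ended without HP1a_KO replicate 1, at -0.07 (adjusted p = 0.569), -0.27 (0.107) and 0.02 (0.807). Without HP1a_KO replicate 2 the cholesterol median was -0.66 and the acute phase median -0.74, and with the Xist level as a covariate the acute phase call ended (-0.31, 0.108) and the female-biased median was -0.27. Limma called 0 genes (324 at an unadjusted p under 0.05, below the 692 that come by chance), edgeR 0 and DESeq2 5. These 5 were Rgs3 (729 against 168 ± 6.81) and the zinc finger gene Zfp655 (2306 against 1159 ± 229.9), which were higher, and Clec2h (4.79 against 370.4 ± 5.52), the immediate early gene Egr1 (36.0 against 414 ± 360.4) and Cbx1, which were lower. The DESeq2 count was 3 without HP1a_KO replicate 1 and 13 without HP1a_KO replicate 2.

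The double mutants were compared with each other as 3 livers against 1. KRAB zinc finger genes did not pass, with a median of -0.02 and 67 of 141 members higher in HP1ag_KO (camera, adjusted p = 0.769, and adjusted p = 0.959 with an estimated correlation). Interferon-stimulated genes were higher in HP1ag_KO in 35 of 45 members by 0.32 (adjusted p = 2.86e-05, and adjusted p = 0.737 with an estimated correlation), or 0.19 without HP1ag_KO replicate 3. Female-biased genes were higher in 28 of 35 by 0.48 (adjusted p = 0.00022, and adjusted p = 0.737 with an estimated correlation), or 0.32 without HP1ag_KO replicate 1 and 0.73 without HP1ag_KO replicate 2. Kupffer cell markers (-0.37, adjusted p = 2.86e-05), stellate cell markers (-0.28, adjusted p = 0.0168), sinusoidal endothelial markers (-0.16, adjusted p = 0.00943), erythroid markers (-1.72, adjusted p = 0.00228) and acute phase proteins (-0.44, adjusted p = 0.000258) were lower, each with adjusted p = 0.737 with an estimated correlation. The endothelial call ended without HP1ag_KO replicate 3 (-0.12, adjusted p = 0.0930) and had a median of -0.24 without HP1ag_KO replicate 2, the acute phase median was -0.66 and -0.23 without HP1ag_KO replicates 1 and 2, and the acute phase call ended with the Xist level as a covariate (-0.20, adjusted p = 0.168). Higher genes in HP1ag_KO were the murinoglobulin Mug2 (27424 ± 5433 against 682), Clec2h (229 ± 142 against 4.79), Mmd2 (456 ± 296 against 57.5), the desmoglein Dsg1c (264 ± 83.2 against 63.9) and Cbx1. Lower were Cyp2c39, Tff3 (109 ± 34.9 against 717), Gpc1 (96.9 ± 3.37 against 301), Wdfy1 (312 ± 20.03 against 703) and Fmr1nb, with 109 reads in HP1ab_KO and 0 in each HP1ag_KO library, where a count of 0 allows up to 3 reads. Limma called 0 genes (750.0 at an unadjusted p under 0.05, 692 by chance), edgeR 0 and DESeq2 13 (8 higher and 5 lower), and 49 without HP1ag_KO replicate 1, 23 without HP1ag_KO replicate 3 or 8 without HP1ag_KO replicate 2.

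Calls of HP1a_KO and HP1ag_KO against the same WT livers overlapped in 0 genes by limma, which called 0 in either, and in 6 genes by DESeq2. Nipal1 and Prlr were higher in both, and Cbx5, Glul, Gstm1 and Nox4 were lower in both, where independent lists would share 0.241 and 0.0922. Cbx5 is the gene deleted in both genotypes, so its sharing follows from the design. The shared genes outside the naming rule were chosen after their values were seen. In 20 simulated sets with no effect, counts were drawn anew for WT, HP1a_KO and HP1ag_KO, and both comparisons used the same drawn WT. DESeq2 then shared a median of 1 higher gene (highest 3) and 0 lower genes (highest 4). The lists were shorter, with a median of 14.5 calls for HP1a_KO and 13 for HP1ag_KO against 89 and 99 in the data. Genes were also drawn independently of each other, so these sets cannot tell how many genes the real libraries would share with no effect. Across genes, which are not independent replicates, the log2 differences of the 2 comparisons correlated at r = 0.279, against 0.486 (-0.438 to 0.917) with no effect. Their covariance was 0.0489 against 0.0407 (-0.0396 to 0.251) simulated, and 56.1% of genes had the same sign against 65.7% (35.4 to 87.4%). Splitting 3 WT livers leaves fewer than 2 on one side, so part of the overlap may come from the shared controls.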

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

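Alternatives chosen only after results were seen were the DESeq2 counts with libraries left out, the DESeq2 overlap, terms for runs of neighbouring animal numbers, and the count tests and Xist covariate for named genes. No paired analysis was run, because the labels name no pairs; neighbouring animal numbers entered only through these terms. Limma's 0 genes in each comparison became, by DESeq2, 99 (HP1ag_KO against WT), 89 (HP1a_KO against WT), 11 (HP1ab_KO against WT), 465 (HP1ag_KO against HP1a_KO), 5 (HP1ab_KO against HP1a_KO) and 13 (HP1ag_KO against HP1ab_KO), and their overlap in HP1a_KO and HP1ag_KO went from 0 to 6. DESeq2 also made more false calls than limma in the simulated counts, and the cause of the differences was not tested. Without a filter, the comparisons of HP1ab_KO with WT, with HP1a_KO and with HP1ag_KO had 54, 56 and 51 calls, all of them genes with a mean under 10, which the filter removes. HP1ag_KO against WT had 2 calls with the Xist level as a covariate (Apobec1 lower and Mt2 higher, chosen after their values were seen). HP1a_KO against WT had 1 with a pseudocount of 5 and 1 with array weights (Cyp2c39 in both). HP1ag_KO against HP1a_KO had 7 without the mean trend and 26 with array weights, and HP1ab_KO against HP1a_KO had 5 in a fit of those groups alone (Clec2h, Cyp7a1 and Mug2 lower, Rps3a2 and Rps3a3 higher, chosen after their values were seen); the cause was not tested.

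Leaving out 1 library at a time gave limma 0 to 2 calls for HP1ag_KO and for HP1ab_KO against WT, 0 to 5 for HP1a_KO against WT and for HP1ag_KO against HP1a_KO, 0 to 1 for HP1ab_KO against HP1a_KO and 0 for HP1ag_KO against HP1ab_KO, with an overlap of 0. The highest counts came without HP1ag_KO replicate 1 (Nox4 lower and Gm13456 higher), WT replicate 3 (Mug2 and Rpl3-ps1 lower) and HP1a_KO replicate 2 (Orm1 and Saa3 among the 5 in each comparison), names chosen after their values were seen. DESeq2 gave 40 to 96 for HP1ag_KO against WT, 4 to 255 for HP1a_KO against WT, 13 to 19 for HP1ab_KO against WT, 26 to 481 for HP1ag_KO against HP1a_KO, 3 to 13 for HP1ab_KO against HP1a_KO and 8 to 49 for HP1ag_KO against HP1ab_KO, and 55 for HP1ag_KO against WT with terms for runs of animal numbers. Those terms left 9 lists past camera for HP1ag_KO against WT: cell cycle (-0.17, 6 of 45 higher, adjusted p = 0.0477), erythroid markers (-0.69, 0.0056) and acute phase proteins (0.26, 0.0477) passed, and the stellate (0.02, 0.313) and fatty acid (0.12, 0.0533) calls ended. Camera with these terms was run at the preset correlation only. Lists past camera numbered 8 to 13, 9 to 12, 9 to 12, 4 to 10, 4 to 8 and 8 to 12 in the same order. Without HP1a_KO replicate 1 the sign turned for cholesterol biosynthesis in HP1ag_KO against HP1a_KO (0.10, or -0.78 without HP1a_KO replicate 2) and for acute phase proteins in HP1ab_KO against HP1a_KO (0.024, or -0.74 without HP1a_KO replicate 2). With an estimated correlation 0 lists passed in any comparison, and with fry 0, except 1 (KRAB zinc finger genes) for HP1ag_KO against HP1a_KO, where the Xist covariate gave 11; the cause was not tested. Of the 48 list calls, TMM scaling left 47 and the Xist covariate 42. Rescaling to equal totals moved the median of all genes by at most 0.0953 on the log2 scale. The 16266423 reads of HP1a_KO replicate 1, the fewest of any library, limit the precision of its low genes.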

Other observations

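Tests chosen only after the result was seen were those of Kupffer cells, female animals, single libraries and less mature livers, and of the calls kept without a library, and the explanation by animal numbers came from looking at other splits of the libraries. Cell cycle genes did not pass in any comparison with WT, with a median log2 difference of 0.05 over 45 members in HP1ag_KO (adjusted p = 0.939, and adjusted p = 0.994 with an estimated correlation), -0.05 in HP1a_KO (adjusted p = 0.789, and adjusted p = 0.94 with an estimated correlation) and 0.06 in HP1ab_KO (adjusted p = 0.584, and adjusted p = 0.985 with an estimated correlation). With terms for runs of neighbouring animal numbers, however, they passed as lower in HP1ag_KO (-0.17, 6 of 45 members higher, adjusted p = 0.0477). That call used the preset correlation only, whereas the list's estimated correlation, without these terms, was 0.719. Imprinted genes did not pass either (0.07 over 27 in HP1ag_KO, adjusted p = 0.428, and adjusted p = 0.782 with an estimated correlation), although Gnas had 6304 ± 98.4 reads against 7478 ± 108 in WT. Genes that mark hepatocytes had medians of 0.02 in HP1ag_KO (adjusted p = 0.939, and adjusted p = 0.994 with an estimated correlation), -0.18 in HP1a_KO (adjusted p = 0.635, and adjusted p = 0.933 with an estimated correlation) and -0.05 in HP1ab_KO (adjusted p = 0.962, and adjusted p = 0.985 with an estimated correlation). Genes of the p53 and DNA damage response had 0.02 in HP1ag_KO (adjusted p = 0.284, and adjusted p = 0.647 with an estimated correlation), with the death receptor Fas at 526 ± 45.0 against 411 ± 27.4. Circadian clock genes had -0.23 (adjusted p = 0.3, and adjusted p = 0.782 with an estimated correlation), and bile acid genes -0.10 (adjusted p = 0.3, and adjusted p = 0.647 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 711 in HP1ab_KO against 6399 ± 5262. The clock genes parted the libraries within WT and within HP1ag_KO. Their mean centred log2 values were 0.30, 0.34 and -0.50 in WT replicates 1 to 3 and -0.50, -0.45 and 0.32 in HP1ag_KO. In HP1a_KO these values lay close, at 0.17 and 0.14.

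KRAB zinc finger genes were higher as a set in HP1ag_KO than in WT by camera at the preset correlation. They did not pass with an estimated correlation (camera adjusted p = 0.135) or by fry (adjusted p = 0.0687). The 1 member that limma called over the list alone, Zfp433, has 84.3% of its 50-base pieces in another gene. The list median lay at the 100th percentile of 10000 random lists matched on mean value, which argues against low levels as the whole cause. The 99 members with under 5% of their 50-base pieces in another gene had a median of 0.22, with 74 higher. The interval of that median (0.13 to 0.32) came from a bootstrap over genes, so it leaves out the spread between livers. The 42 members at 5% or more had a median of 0.20, so shared reads are argued against as the whole cause. Terms for runs of neighbouring animal numbers left 0.16 (camera at the preset correlation, adjusted p = 2.5e-07), which argues against animal numbers as the whole cause. With these terms 5 libraries carry the comparison and WT replicate 1 has no weight. More Kupffer cells as the whole cause are argued against by HP1ag_KO against HP1a_KO, where the KRAB median was 0.31 while that of 16 Kupffer cell markers, all of them expressed in WT and 0 in another list, was -0.37, and by HP1a_KO against WT (-0.12 and 0.56), although both lists were higher in HP1ag_KO against WT (0.21 and 0.20) and in HP1ab_KO against WT (0.22 and 0.53); of these markers Slc40a1 had 5483 ± 544 reads in HP1ag_KO and 8055 ± 291 in HP1a_KO. Stellate cell markers also moved opposite to KRAB genes in these 2 comparisons (-0.25 in HP1ag_KO against HP1a_KO and 0.31 in HP1a_KO against WT), but endothelial, cholangiocyte and lymphocyte markers did not pass in either, so such cells stay open. Both comparisons rest on the same 2 HP1a_KO livers, whose animal numbers are adjacent. The real split gave a camera p of 9.72e-10, as small in 1 of 10 splits (next 1.65e-06), too few splits for a share under 0.05. The genotype may account for the difference, beside such cells, as a hypothesis found and tested on the same libraries.

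Female-biased genes were higher and male-biased genes lower in HP1ag_KO than in WT by camera at the preset correlation. Neither list passed with an estimated correlation (camera adjusted p = 0.647 for each). Female animals are argued against by the Y-linked genes, whose lowest level in an HP1ag_KO library was 79.7% of the WT mean. A single HP1ag_KO library as the whole cause is argued against for female-biased genes, whose median was 0.58 at the nearest to 0, without replicate 1 (adjusted p = 3.17e-06). Replicate 1 stood apart even so: the mean centred log2 values of these genes were 1.73, -0.25 and 0.42 in HP1ag_KO replicates 1 to 3 and -1.21, -0.13 and -0.74 in WT, so replicate 2 lay below WT replicate 2. A single library may account for much of the male-biased difference, which was -0.28 without HP1ag_KO replicate 1. The test was split into female- and male-biased genes after their values were seen. Terms for animal numbers left 0.61 and -0.84 (camera at the preset correlation, adjusted p = 9.9e-06 and 2.17e-05). With these terms 5 libraries carry the comparison and WT replicate 1 has no weight. Less mature livers may also contribute, on weak grounds: 10 of 12 listed genes that fall after birth were tested and 8 were higher. Their median was 0.44, and its interval over genes (0.12 to 0.88) leaves out the spread between livers. The widest differences were 3.16 ± 1.17 SE for H19 and 1.32 ± 0.24 SE for Gpc3. The others lay between -0.25 ± 0.28 SE (Grb10) and 0.60 ± 0.44 SE (Igf2bp3). The list of fetal liver and hepatocellular carcinoma markers, with a median of 0.18, did not pass. The genotype stays open beside these, since slower maturation and the genotype were not separated.

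DESeq2 calls against WT numbered 99 for HP1ag_KO. Of the 10 splits of the 6 libraries 3 gave as many, the real one among them (highest other 320), and 10 splits are too few for a share under 0.05. Other splits giving as many was the outcome set beforehand for a grouping by chance, so this count does not set the genotype grouping apart. The split with 320 calls put WT replicates 1 and 2 with HP1ag_KO replicate 3 against the others. It also gave limma 23 calls and parts no run of neighbouring animal numbers (gaps of up to 50), and so many calls point to a structure of the samples. Yet WT replicates 1 and 3 with HP1ag_KO replicate 1 against the others, which keeps both pairs of adjacent numbers together but parts a run, gave 0 limma calls (707 at an unadjusted p under 0.05) and 31 by DESeq2, so what the structure follows is not settled. Circadian clock genes, a list picked after its values were seen, parted the 6 libraries as the split with 320 calls did. Their centred means were 0.30, 0.34 and 0.32 in WT replicates 1 and 2 and HP1ag_KO replicate 3. They were -0.50, -0.50 and -0.45 in WT replicate 3 and HP1ag_KO replicates 1 and 2. The cause was not tested. With terms for runs of such numbers 35 of the 99 calls stayed past the threshold, all 99 kept their sign and 55 genes were called; 35 is under 50%, the share set beforehand as the sign of such a cause. But the terms also give no weight to WT replicate 1, alone in its run. Leaving out that library with no terms kept 34 of the 99 (45 to 55 without another library), a comparison added after the 35 was seen. Its animal number (63) also lies far from those of the other WT and HP1ag_KO livers. The lost calls thus cannot tell animal numbers from the loss of that library. The median absolute log2 fold of the 99 was 1.03 without the terms and 1.01 with them, and their median SE 0.252 and 0.262. With the terms 5 libraries carry the comparison, so how far animal numbers account for these calls stays open. DNA of the other strain near the targeted genes is argued against as the cause of more than 3.73% of the HP1ag_KO calls, the upper limit for 0 of 97 calls within 10 Mb, where 1.51% of tested genes lie (one-sided Fisher's exact p = 1); a smaller share stays open. For HP1a_KO 2 of 87 calls (Ano6 and Zfp385a, named after their values were seen) lay within 10 Mb of Cbx5, 2.30% against 0.845% of tested genes (one-sided Fisher's exact p = 0.167, upper limit 8.06%), too few to decide, and it may contribute. Both tests cover only genes within 10 Mb, and DNA of the other strain elsewhere was not tested.

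Genes at an unadjusted limma p under 0.05 numbered 1050 for HP1ag_KO against WT, and 3 of the 10 splits gave as many (highest other 1363). Lists past camera numbered 8, and 9 of the 10 splits gave as many (highest other 13). The real split is among these 3 and 9. Other splits giving as many was the outcome set beforehand for a grouping by chance, so neither count sets the genotype grouping apart. Even a highest count would not have decided, as 10 splits are too few for a share under 0.05.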
